A study of Mus musculus with 14 samples.

How the data were processed

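RNA was measured in the livers of 14 mice, 7 WT and 7 Cyp2c29 KO, all on the same diet for 16 weeks, and the groups and replicate numbers were taken from the sample labels. Per the labels' protocols, ribosomal RNA was removed from total RNA, and an Illumina NovaSeq gave each animal a depth above 140 M reads. The submitters' processing notes name Salmon, which estimates transcript abundance from reads, and the mouse genome build mm39. The version of Salmon, the annotation and the scaling steps are not given in the sources used here. The deposited files hold 1 log2 value per gene for each library, and the unit log2 is taken from the values themselves, which run from 0 to about 21 and give linear sums of 35.2 M or more as 2 to the power of the value minus 1. A value taken at the same high rank in each library lay within 12.27 to 12.35 in the 14 libraries, so the authors' values appear scaled to a common level, by a rule that is not stated. Whether low values are whole multiples of a common step was checked on 2 to the power of the value, without subtracting 1. The step was set from the most frequent low value of each library. Between 27.5% and 38.4% of low values came out whole, within a tolerance of 0.1. Because 1 was not subtracted, the check cannot decide whether scaled counts underlie the values, and read counts were not recovered. The depth behind each value is therefore known only from the protocol, and no counting interval is given.

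The planned test was a count-based one. Because the deposited unit is log2 and not counts, limma-trend was used in its place. Each library was rescaled by a trimmed mean of log ratios (30% of genes trimmed by ratio and 5% by level), which shifted the libraries by −0.12 in KO 6 to 0.28 in WT 3 on the log2 scale. Genes were tested if their linear value reached 10 in at least 7 libraries, which kept 18602 of 76989 genes (24.2%). Of the 76989, 21818 carry an Ensembl identifier in place of a symbol. The model compared KO with WT with no other term, p-values were adjusted by the method of Benjamini and Hochberg, and fold changes are on the scale of log2 of the value plus 1, which understates the changes of low genes. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9, were used.

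Before the data were examined, 43 gene lists for pathways and cell types, the rule for the genes named in the text, the model and most alternatives were fixed. The lists hold 1080 genes, of which 1009 were tested and 6 have no value under the listed symbol. Each list was scored in each animal as the mean rescaled log2 value of its tested members, and the group difference was tested by an exact two-sided permutation of the group labels, adjusted over the 43 lists. The smallest p this allows is 0.000583 with 7 against 7 libraries and 0.00303 with 4 against 7. Camera with a preset correlation of 0.01, camera with an estimated correlation and fry were run beside it. Camera compares a list with other genes, and fry asks whether the genes of a list move one way. With a preset correlation camera passed 32 lists, fry passed 20, and with an estimated correlation camera passed none at an adjusted p and 3 at an unadjusted p below 0.05.

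The named genes are every tested Cyp2c gene, the 12 genes per direction with the largest change among those called with the same direction in all 14 fits that leave out 1 library (with a mean of at least 1 CPM, as a share of the linear sum, and a symbol that is not a predicted-gene or RIKEN name), up to 4 members per list with the smallest p, and the 5 called genes of highest mean. The same rule was applied to the 11 libraries with Xist after the data were seen. Some genes, such as Muc1 and Cps1, are named under more than 1 part of the rule, and some that the rule selects are not used here. Genes near Cyp2c29 were taken from a GRCm38 annotation, matched by symbol for 15586 tested genes; this is not the build of the deposited files, so it served only for the order of genes and for which genes lie close together, and no coordinates are given. Sharing of sequence between Cyp2c29 and other Cyp2c transcripts was counted as shared stretches of 31 bases in GRCm38 transcripts.

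The alternatives were median-ratio scaling, no filter, a stricter filter of 1 CPM in at least 7 libraries, offsets of 0.1 and 0.5 in place of 1, a block for the replicate number, leaving out each library, other list tests and scores, and windows of 5 and 20 Mb around Cyp2c29. Added after the data were seen were the values as deposited, array quality weights, the 11 libraries with Xist, a term for the Y-linked signal over 14 libraries, and the 11 libraries without WT 3. Libraries were compared with one another: the highest correlation of each with another lay between 0.916 and 0.950, and at most 40 tested genes had identical values in any pair, so all 14 were counted as separate samples.

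The test was tested on simulated data made from the real gene means and spreads with 100 genes changed by 1 and 100 by 2 on the log2 scale. With 7 against 7 libraries and 18602 genes it recovered 55% and 84% of them, with a false share of 6.71% among its calls, and with 4 against 7 libraries 37% and 71%, with a false share of 9.24%. The spreads were those left after the genotype and the Y-linked signal were fitted, and genes were drawn independently. No sex imbalance or deviating library was simulated, so these shares need not hold for the real comparisons.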

Results

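Liver RNA was profiled from 14 mice, 7 wild-type (WT) and 7 carrying a knockout of Cyp2c29 (KO), a mouse cytochrome P450 of the Cyp2c subfamily whose substrates include arachidonic acid. All mice had eaten a choline-deficient, amino-acid-defined high-fat diet for 16 weeks, a regimen that produces steatohepatitis and liver fibrosis in mice. The series title names a role of the enzyme in that fibrosis, so the comparison of KO with WT livers addresses which genes of scarring, inflammation and liver metabolism differ when Cyp2c29 is lost under this diet. The labels give total RNA libraries depleted of ribosomal RNA and sequenced to a depth above 140 M reads each. The deposited values are log2 numbers for 76989 genes, and their linear sums were 35.2 M in KO 4 and higher in the other libraries. Between 24909 genes (KO 7) and 29285 genes (WT 5) had a value above 0. Differences between groups are given on the log2 scale after rescaling of the libraries, with the standard error of the limma fit after ±. The limma and exact permutation p-values rest on the spread between animals. Fisher's exact p-values, given for genes near Cyp2c29, take genes as units and treat them as independent, and do not measure that spread.

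The labels do not give the sex of the mice. Xist, the RNA that silences one X chromosome in females, had deposited log2 values of 14.08 to 15.06 in WT 1 to 4 and in all 7 KO libraries, and of 0 to 4.22 in WT 5, 6 and 7. The mean of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 11.36, 11.08 and 11.24 in WT 5, 6 and 7 and at most 0.64 in the other 11 libraries. Many results are therefore given over 14 libraries and also over the 11 libraries with Xist signal, 4 WT and 7 KO, a comparison chosen after the data were seen. WT 3 stood apart on the first principal component of these 11 libraries, at 136, with the other 10 between −64.0 and 55.2.

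**Figure D1:**
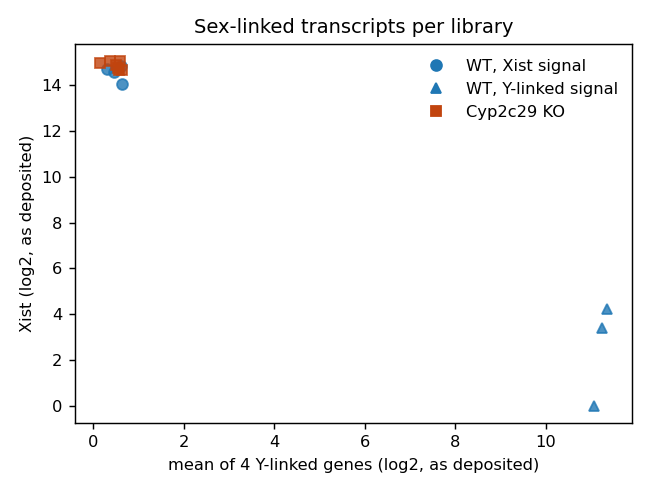
Each point is 1 library, with the mean deposited log2 value of 4 Y-linked genes on the x axis and that of Xist on the y axis. The 11 libraries with Xist lie at 14.08 or above, and the 3 WT libraries with Y-linked signal lie at 4.22 or below.

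Cyp2c29 was high in every WT liver and near 0 in every KO liver. Its linear values were 5243 to 7432 in WT 1 to 4 and 1004 to 1311 in WT 5 to 7. In KO libraries it was listed at 0 in 4 and at 3.92, 9.80 and 17.7 in the other 3, and its log2 value fell by 10.01 ± 0.80 over 14 libraries (limma adjusted p = 1.54e-05) and by 11.11 ± 0.86 over the 11. The files also list a feature named Cyp2c29KO, which the labels do not describe. Its linear values were 45507 to 79721 in the KO libraries, 289 to 492 in WT 1, 3, 4 and 5, and 0 to 0.665 in WT 2, 6 and 7. The Cyp2c29 values thus separate the libraries as their genotype labels state. What sequence the Cyp2c29KO feature stands for is not known. Its value in every KO library exceeded the Cyp2c29 value of every WT library, so RNA assigned to both features together was higher in KO. How reads were divided between these features was not tested.

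**Figure D2:**
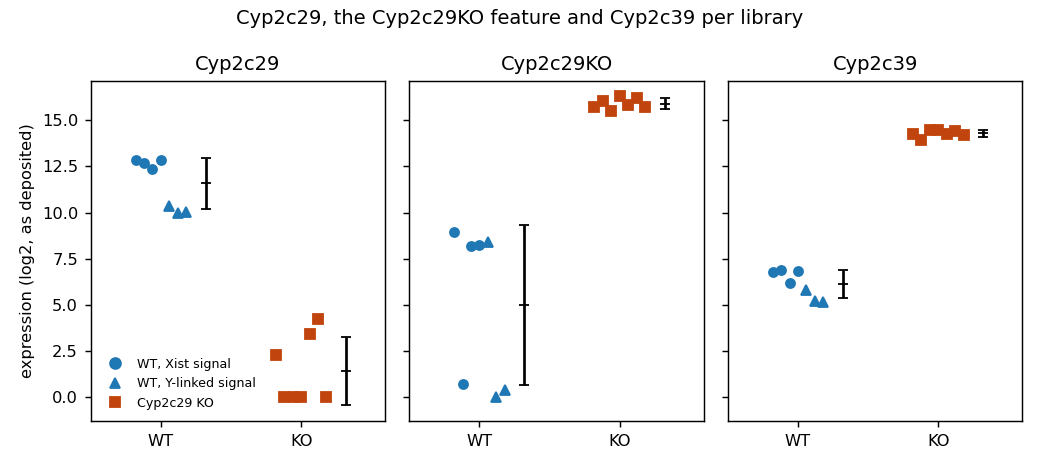
Deposited log2 values of Cyp2c29, of the feature named Cyp2c29KO and of Cyp2c39 in each library, with the mean and SD of each group of 7 beside the points. Cyp2c29 lies between 9.97 and 12.86 in WT and at or below 4.23 in KO, while Cyp2c39 lies at or below 6.91 in WT and at or above 13.94 in KO.

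Among the neighbouring Cyp2c genes, which encode related monooxygenases, Cyp2c39 rose most. Its deposited log2 value was 5.13 to 6.91 in WT and 13.94 to 14.48 in KO, a rise of 8.30 ± 0.27 (limma adjusted p = 1.35e-10) and of 7.76 ± 0.17 over the 11 libraries. Cyp2c38 rose by 1.71 ± 0.37 and Cyp2c37 by 1.45 ± 0.27, and by 0.97 and 1.05 over the 11 libraries. With WT 3 left out of these as well, Cyp2c38 no longer passed (0.82, limma adjusted p = 0.0965), while Cyp2c37 did (0.69, limma adjusted p = 0.0318). Cyp2c55 fell by 2.06 ± 0.32, and by 2.35 over the 11 libraries. Cyp2c70 rose by 1.09 ± 0.26, but its difference of 0.79 over the 11 libraries had an adjusted p of 0.0955. Cyp2c68 differed by −0.46 ± 0.18 over 14 libraries (adjusted p = 0.0761) and fell by 0.77 over the 11 (adjusted p = 0.0169). The differences of Cyp2c23 (0.36 ± 0.16), Cyp2c50 (−0.10 ± 0.41), Cyp2c54 (0.56 ± 0.74), Cyp2c67 (−0.31 ± 0.23), Cyp2c40 (0.66 ± 1.09) and Cyp2c69 (3.71 ± 1.79) did not pass. Cyp2c40 and Cyp2c69 took the opposite sign over the 11 libraries, at −1.70 and −0.25. When 1 library was left out, Cyp2c40 ran from 0.069 to 1.17 and Cyp2c67 from −0.51 to −0.23, and Cyp2c67 passed without WT 3. The list of Cyp2c genes other than Cyp2c29, of which 12 were measured, rose by 1.24 (WT 10.38 ± 1.11, KO 11.63 ± 0.20, SD, n = 7, exact permutation adjusted p = 0.0376) with 4 members higher and 1 lower, or 4 and 2 adjusted over the list alone. The median member differed by 0.61, against 8.30 for Cyp2c39. The list did not pass over the 11 libraries (0.53, exact permutation adjusted p = 0.139; 0.085 when WT 3 was left out as well), nor without any single KO library (adjusted p = 0.0534 to 0.0778), and its adjusted p was 0.593 with an estimated correlation. Reads of these paralogs can be shared: 109 of the 1787 stretches of 31 bases in the annotated Cyp2c39 transcript (6.1%) also occur in Cyp2c29 transcripts. The value of Cyp2c39 is uncertain for that reason, and this share does not give the size of the possible error. The share was 2.85% for Cyp2c38, 0.71% for Cyp2c68, 0.39% for Cyp2c37, 0.15% for Cyp2c55 and 0 for Cyp2c40 and Cyp2c70. Sharing among members other than Cyp2c29, or with the undescribed Cyp2c29KO feature, was not counted.

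Genes near Cyp2c29 were called more often than the rest. In the GRCm38 annotation the order along the chromosome is Cyp2c55, Cyp2c65, Cyp2c66, Cyp2c29, Cyp2c39, Cyp2c38, Cyp2c67, Cyp2c68, Cyp2c40, Cyp2c69, Cyp2c37, Cyp2c54, Cyp2c50 and Cyp2c70. Within 10 Mb on either side, 56 of 191 tested genes passed (29.3%), against 22.1% of the other 15394 placed genes (odds ratio 1.46, one-sided Fisher's exact p = 0.0128). Without the Cyp2c genes it was 51 of 179 (Fisher's exact p = 0.0282), and over the 11 libraries 35 of 191 with them (p = 0.0348) and 30 of 179 without them (p = 0.118). The odds ratio was 1.02 on the values as deposited (Fisher's exact p = 0.481), and the result was lost without WT 1, 4, 6 or 7 or KO 1, 2, 3 or 5 (odds ratios 1.18 to 1.34).

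Over the whole liver transcriptome, 3737 of 18602 tested genes differed between KO and WT at an adjusted p below 0.05 in limma, 1918 higher and 1819 lower in KO. Drug-metabolising and bile acid genes, hepatocyte zonation genes and genes of female-biased expression were prominent on the higher side. Collagens, proteases, myeloid and ductular markers, ribosomal protein genes and immediate early genes were prominent on the lower side. Over the 11 libraries with Xist 2275 genes differed, 1207 higher and 1068 lower, of which 1980 were among the 3737, all in the same direction. Without rescaling, 4137 genes passed with 1041 higher and 3096 lower, so the share of higher genes was 25.2% in place of 51.3%, and the median log2 difference of all genes was −0.157 in place of −0.0112. Over the 11 libraries the unrescaled values gave 720 higher and 1776 lower. Leaving out WT 3 from the 11 libraries left 964 genes, 602 higher and 362 lower.

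The genes with the largest rises that held in all 14 fits leaving out 1 library included, besides Cyp2c39 and the Cyp2c29KO feature, several other cytochrome P450 genes. A1bg, a plasma glycoprotein gene, rose by 6.87 ± 1.80 and Cyp3a41a by 6.13 ± 1.41. Cyp3a41b rose by 5.21, Cyp2b13 by 4.82, Cyp3a16 by 4.21, Acot3, a peroxisomal acyl-CoA thioesterase, by 3.49, Tafa2, a secreted peptide, by 3.02, Cyp2b9 by 2.90 and the steroid hydroxylase Cyp17a1 by 2.84. The rises were smaller among the 11 libraries, at 2.92 for A1bg, 2.33 for Cyp2b13, 3.45 for Cyp3a16, 1.83 for Acot3, 2.12 for Tafa2 and 1.26 for Cyp2b9. Cyp3a41a (3.40, adjusted p = 0.0546), Cyp3a41b (3.601, adjusted p = 0.150) and Cyp17a1 (1.39, adjusted p = 0.0901) no longer passed there. With WT 3 left out of the 11 libraries as well, A1bg and Tafa2 did not pass either (limma adjusted p = 0.140 and 0.0786). Cyp2b13, Cyp3a16, Acot3 and Cyp2b9 still did (limma adjusted p = 0.0162, 0.0395, 0.0226 and 0.0114). Cyp3a41a, Cyp3a41b, Cyp4a12a, Cyp4a12b, Mup6 and Ccl21d have near-identical paralogs, and their values are uncertain for that reason.

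On the lower side, besides Cyp2c29, stood Cyp4a12b (−5.30 ± 1.02) and Cyp4a12a (−4.57 ± 1.01), omega-hydroxylases of arachidonic acid, the vomeronasal receptor gene Vmn2r3 (−5.15), the chemokine gene Ccl21d (−4.39) and the calcium channel gene Cacna1s (−3.73). Mmp7, which encodes the epithelial protease matrilysin, fell by 3.69 ± 0.48, Scara5, a ferritin receptor gene, by 3.49, Fam169a by 3.45, and the asparagine synthetase gene Asns by 3.22. The major urinary protein gene Mup6 (−3.20) and the ubiquitin hydrolase gene Uchl1 (−3.14) followed. Mmp7 (−3.37), Uchl1 (−2.74), Cyp4a12b (−3.33), Scara5 (−1.80) and Fam169a (−3.28) passed over the 11 libraries too. Cyp4a12a (−2.95), Vmn2r3 (−4.05), Ccl21d (−4.15), Cacna1s (−3.74), Asns (−1.66) and Mup6 (−2.39) did not, with adjusted p-values of 0.0542 to 0.0914. With WT 3 left out of the 11 libraries as well, Mmp7 and Uchl1 still passed (limma adjusted p = 0.0213 and 0.0387). Cyp4a12b, Scara5 and Fam169a no longer did (limma adjusted p = 0.0702, 0.0808 and 0.0610).

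Chosen by the same rule within the 11 libraries, further genes came to the front. Dynlt2a1, a dynein light chain gene, rose by 4.92 ± 0.82, Tiam2, an activator of the GTPase Rac, by 2.55 ± 0.41, Cyp2g1 by 2.51 ± 0.21, the mitochondrially encoded oxidase subunit mt-Co3 by 2.22 ± 0.43, the fructose transporter gene Slc2a5 by 2.11 ± 0.39, the uridine phosphorylase gene Upp2 by 1.90 ± 0.32 and Cyp2j11 by 1.62 ± 0.29. Erich2 fell by 3.496, Igfbp1, which binds insulin-like growth factors, by 2.86, the clock repressor gene Cry1 by 2.33, Mycbpap by 2.24, the reelin adaptor gene Dab1 by 2.03, the potassium channel gene Kcnh7 by 1.99, the epithelial mucin gene Muc1 by 1.99 and the secreted protein gene Scube3 by 1.93. Over 14 libraries Dynlt2a1, mt-Co3, Slc2a5, Cry1 and Kcnh7 did not pass (adjusted p = 0.0739 to 0.199). The mean rescaled log2 value of Dynlt2a1 was 0.29, near the floor, in the WT libraries with Xist. It was 5.19 in the WT libraries with Y-linked signal and 5.21 in KO. Among the most abundant changed genes, the urea cycle genes Cps1 and Ass1 rose by 1.05 ± 0.18 and 0.54 ± 0.16, the esterase gene Ces1c by 0.87 ± 0.21 and the selenium carrier gene Selenop by 0.53 ± 0.17. Over the 11 libraries Cps1 (1.11) and Ass1 (0.60) passed while Ces1c and Selenop did not (adjusted p = 0.0892 and 0.132). The call of Selenop ended in 9 of the 14 fits that leave out 1 library, and held without WT 1, 2, 3 or 7 or KO 4. That of Ass1 ended in 9 and held without WT 1, 6 or 7 or KO 2 or 3.

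Genes of the scar matrix were lower in KO livers. The list of fibrillar collagen and matrix assembly genes fell by 0.51, from 10.59 ± 0.37 in WT to 10.08 ± 0.22 in KO (SD, n = 7, exact permutation adjusted p = 0.0277), and by 0.65 over the 11 libraries (adjusted p = 0.0186). All 7 KO libraries lay below the WT mean. Of 38 measured members 15 fell and none rose, or 26 fell and 1 rose adjusted over the list alone. Col1a1 and Col1a2, the chains of type I collagen, fell by 0.69 ± 0.18 and 0.70 ± 0.16, Col16a1 by 0.79 ± 0.20, and Emilin1, an elastic fibre glycoprotein gene, by 0.63 ± 0.13. Basement membrane genes fell by 0.64 (exact permutation adjusted p = 0.00557), with 9 of 18 members lower, or 12 adjusted over the list alone, among them Lama5, a laminin chain gene (−1.62 ± 0.32), and Col4a2 of type IV collagen (−0.75 ± 0.16). Matrix proteases and their inhibitors fell by 0.82 (adjusted p = 0.00418), with 11 of 22 members lower and 1 higher, or 14 and 1 adjusted over the list alone. Adam8 fell by 1.23 ± 0.18 and the macrophage elastase gene Mmp12 by 1.19 ± 0.22, whereas Mmp19 rose by 0.71 ± 0.11. The list of TGF-beta signalling and its targets fell by 0.51 (adjusted p = 0.00418), with 11 of 25 lower and none higher, or 13 adjusted over the list alone. Ccn2, a profibrotic target of this pathway, fell by 1.22 ± 0.19, and Itgb6, an integrin subunit that activates latent TGF-beta, by 1.55 ± 0.28. Over the 11 libraries these 3 lists fell by 0.72, 0.88 and 0.53 (exact permutation adjusted p = 0.0186 for each). Against other genes, the adjusted p of these 4 lists was 0.324 to 0.402 with an estimated correlation, and the collagen list no longer passed without KO 3 (adjusted p = 0.0589) or KO 6 (0.0646), or in the 11 libraries without WT 3 (−0.54, adjusted p = 0.0597), where no list passed after adjustment and 18 did at an unadjusted p.

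The stellate cell and myofibroblast markers differed by −0.24 as a list (exact permutation adjusted p = 0.157), and by −0.31 to −0.15 when 1 library was left out, with 4 of 25 members lower and 1 higher, or 9 and 2 adjusted over the list alone. Vim, which rises when stellate cells activate, fell by 0.88 ± 0.15. Lrat, which stores vitamin A in quiescent stellate cells, rose by 0.65 ± 0.12.

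Myeloid and inflammatory genes were lower in KO. The list of macrophage and recruited myeloid markers fell by 0.68 (WT 11.28 ± 0.30, KO 10.60 ± 0.16, SD, n = 7, exact permutation adjusted p = 0.00418), with every KO library below every WT library and a fall of 0.67 over the 11. Of 32 members 22 fell and none rose, or 26 adjusted over the list alone. Itgam, an integrin of myeloid cells, fell by 1.38 ± 0.21, Trem2, a receptor of lipid-associated macrophages, by 1.09 ± 0.16, and the lysozyme gene Lyz2 by 0.91 ± 0.14. Neutrophil markers fell by 0.92 (adjusted p = 0.00578), with 4 of 12 members lower over all genes and over the list alone. S100a8 and S100a9, the subunits of calprotectin, fell by 1.13 ± 0.27 and 1.08 ± 0.24, although S100a8 had an adjusted p of 0.0701 over the 11 libraries. Chemokines and inflammatory cytokines fell by 0.35 (adjusted p = 0.00578), with 11 of 31 lower and 3 higher, or 12 and 3 adjusted over the list alone. Ltb, a lymphotoxin gene, fell by 1.19 ± 0.24 and the chemokine gene Cxcl14 by 0.78 ± 0.13, while Cxcl11, an interferon-induced chemokine gene, rose by 0.82 ± 0.17. The neutrophil and chemokine lists fell by 0.99 and 0.41 over the 11 libraries (exact permutation adjusted p = 0.0230 for both), and the adjusted p of the 3 lists was 0.324 to 0.342 with an estimated correlation. Kupffer cell markers did not pass as a list (0.35, adjusted p = 0.157; 0.22 to 0.45 when 1 library was left out), with 4 of 15 members higher and none lower, or 5 adjusted over the list alone. The list differed by 0.17 over the 11 libraries, where no member passed in limma over all genes or over the list alone (4 higher and 1 lower did at an unadjusted p), and by 0.016 when WT 3 was left out as well. Among the members higher over 14 libraries was the iron exporter gene Slc40a1 (0.44 ± 0.10), which did not pass over the 11 libraries (adjusted p = 0.0684).

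Bile duct and ductular genes fell by 0.97 as a list (WT 9.07 ± 0.42, KO 8.10 ± 0.37, SD, n = 7, exact permutation adjusted p = 0.00578), and by 1.05 over the 11 libraries. Of 22 members 15 fell and none rose, or 16 adjusted over the list alone. They included Spp1, the osteopontin gene (−1.17 ± 0.20), the biliary transcription factor gene Sox9 (−1.03 ± 0.18), Cd24a (−1.28 ± 0.22), and the mucin gene Muc1 (−1.83 ± 0.33). Markers of liver tumours and fetal liver fell by 0.59 (exact permutation adjusted p = 0.0338), and by 0.82 over the 11 libraries, with 7 of 21 lower and 1 higher both over all genes and over the list alone. Cd44, a hyaluronan receptor gene, fell by 0.65 ± 0.13, the axon guidance receptor gene Robo1 rose by 1.04 ± 0.19, and Myc fell by 0.99 ± 0.22. The adjusted p was 0.324 for the ductular list and 0.416 for the tumour list with an estimated correlation. The liver tumour and fetal liver markers list no longer passed without WT 3, 4 or 5 or KO 3, 4, 5, 6 or 7 (adjusted p = 0.0501 to 0.0799). WT 3, which stood apart from the other libraries, had the highest ductular list value, and without it the difference of the 10 libraries was −0.86.

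**Figure D3:**
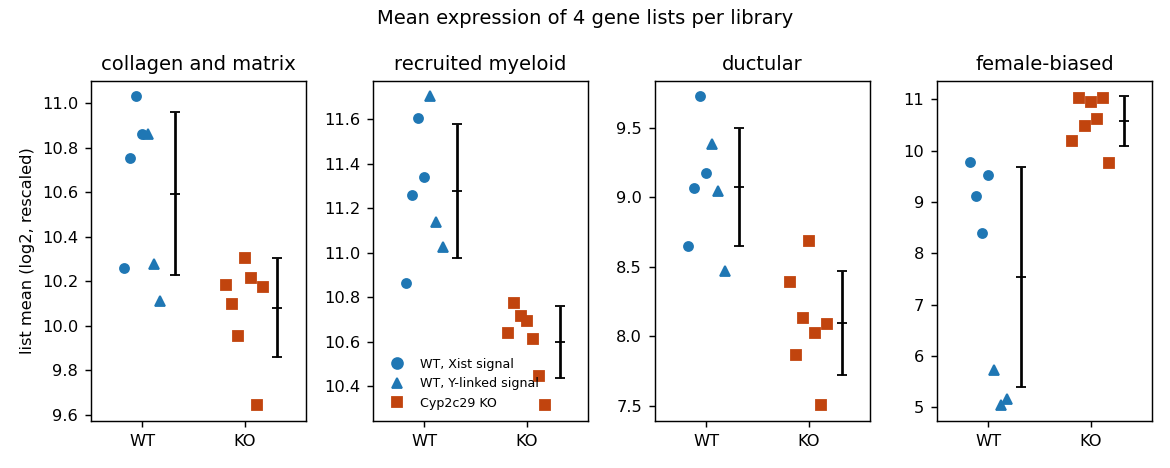
Mean rescaled log2 expression of 4 gene lists in each library, with the mean and SD of each group of 7 beside the points. For the collagen and matrix, myeloid and ductular lists the KO mean lies below the WT mean (10.08 against 10.59, 10.60 against 11.28 and 8.10 against 9.07), and for the female-biased list it lies above it (10.57 against 7.53).

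Genes of both hepatocyte zones were higher in KO. Periportal genes rose by 0.51 (exact permutation adjusted p = 0.00418), with 9 of 21 members higher and none lower, or 11 adjusted over the list alone, and every KO library above every WT library. Examples were the urea cycle genes Cps1 (1.05 ± 0.18) and Arg1 (0.78 ± 0.19) and the glutaminase gene Gls2 (0.77 ± 0.16). Pericentral genes rose by 0.51 (adjusted p = 0.00578), with 9 of 25 higher and 1 lower, or 11 and 1 adjusted over the list alone. Oat, an ornithine aminotransferase gene of the pericentral zone, rose by 1.12 ± 0.18. Genes of hepatocyte synthetic function rose by 0.29 (adjusted p = 0.0376), with 8 of 33 higher and none lower over all genes and over the list alone. Over the 11 libraries the 3 lists rose by 0.44, 0.63 and 0.32 (exact permutation adjusted p = 0.0186, 0.0186 and 0.0274), and with WT 3 left out as well they differed by 0.41, 0.37 and 0.20. WT 3 was the lowest WT library of the pericentral list. With an estimated correlation the adjusted p of the 3 lists was 0.324, 0.416 and 0.560. The pericentral and synthetic function lists did not pass with fry (adjusted p = 0.0561 and 0.0654). The synthetic function list did not pass on the values as deposited, nor without WT 3 or 5 or KO 1, 2, 3, 5, 6 or 7 (adjusted p = 0.0512 to 0.0877). Alb, Ass1, Cps1 and Serpina1c stand on both the periportal and the synthetic function lists, so these rises are not fully separate results. The pericentral list includes Cyp2c37, Cyp2c50 and Cyp2c54, which lie in the same gene cluster as Cyp2c29.

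Targets of the nuclear receptors CAR and PXR and genes of drug metabolism rose by 1.16 (WT 11.03 ± 0.46, KO 12.19 ± 0.24, SD, n = 7, exact permutation adjusted p = 0.00418), with every KO library above every WT library. Of 44 measured members 23 rose and none fell, or 25 adjusted over the list alone. Beyond Cyp2b9, Cyp2b13 and Cyp3a16 they included Cyp3a25 (1.10 ± 0.18), Sult1d1, a sulfotransferase gene (0.87 ± 0.13), and Ugt1a1, which conjugates bilirubin (0.67 ± 0.12). The rise was 0.83 over the 11 libraries (exact permutation adjusted p = 0.0186), with 14 higher, or 22 adjusted over the list alone. The female-biased liver genes rose by 3.04 (WT 7.53 ± 2.14, KO 10.57 ± 0.48, exact permutation adjusted p = 0.00557), with 18 of 25 higher and none lower, or 20 adjusted over the list alone. Over the 11 libraries, which leave out the WT libraries with Y-linked signal, they rose by 1.37 (adjusted p = 0.0186), with 10 higher, or 15 higher and 1 lower adjusted over the list alone. Hao2, a peroxisomal oxidase gene, rose by 2.82 ± 0.53 and Trim24, a transcriptional cofactor gene, by 1.02 ± 0.13, and by 1.83 and 0.79 over the 11 libraries. The male-biased genes differed by −1.20 over 14 libraries (adjusted p = 0.177; it passed without WT 3) and by 0.11 over the 11 (adjusted p = 0.877). With an estimated correlation the adjusted p of the CAR and PXR list and of the female-biased list was 0.324. The median member of the CAR and PXR list differed by 0.49 over 14 libraries and by 0.52 over the 11. Cyp2a4, Cyp2b9, Cyp2b13, Cyp3a16, Cyp3a41a, Cyp3a41b, Cyp3a44, Sult2a1 and Sult3a1 stand on both lists. The rises of the CAR and PXR list and of the female-biased list are therefore not separate results.

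Bile acid genes rose by 0.40 (exact permutation adjusted p = 0.0150), with 14 of 31 higher and none lower, or 16 higher and 1 lower adjusted over the list alone, and by 0.48 over the 11 libraries. The sterol exporter genes Abcg5 and Abcg8 rose by 1.13 ± 0.13 and 0.87 ± 0.14, the organic anion transporter gene Slco1a4 by 1.47 ± 0.20, and Klb, a coreceptor gene for fibroblast growth factors, by 0.77 ± 0.12. Choline, methionine and phospholipid metabolism rose by 0.18 (adjusted p = 0.0265), with 13 of 32 higher and 4 lower, or 16 and 5 adjusted over the list alone, and by 0.21 over the 11 libraries. The folate-linked genes moved apart, with Shmt1, the cytosolic hydroxymethyltransferase gene, up by 1.06 ± 0.17 and Mthfd2, the mitochondrial dehydrogenase gene, down (−1.43 ± 0.17). Chkb, a choline kinase gene, fell by 0.56 ± 0.11. With WT 3 left out of the 11 libraries the bile acid list differed by 0.29 and the choline list by 0.12. With an estimated correlation the adjusted p was 0.324 for the bile acid list and 0.416 for the choline list. The choline, methionine and phospholipid metabolism list did not pass on the values as deposited, nor without KO 1, 4, 5, 6 or 7 (adjusted p = 0.0534 to 0.0835).

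The lists of fatty acid synthesis, fatty acid oxidation, lipid droplets and cholesterol synthesis did not pass the exact permutation test over 14 libraries. Fatty acid and triglyceride synthesis differed by 0.43 (exact permutation adjusted p = 0.0626), with 6 of 28 members higher and 2 lower, or 8 and 2 adjusted over the list alone. The fatty acid and triglyceride synthesis list did pass without WT 1, WT 6 or KO 2, as a mean of z-scores (adjusted p = 0.0303) and with fry (0.0465). It did not pass over the 11 libraries (0.51, exact permutation adjusted p = 0.0850) or with camera's estimated correlation (adjusted p = 0.430). Srebf1, the lipogenic transcription factor gene, rose by 0.91 ± 0.17 and Dgat2, which makes triglyceride, by 0.80 ± 0.15, while the desaturase gene Scd2 fell by 0.80 ± 0.14. The list of PPARA targets and fatty acid oxidation differed by 0.15 (adjusted p = 0.249), and by 0.079 to 0.20 when 1 library was left out, with 9 of 43 higher and 2 lower, or 11 and 2 adjusted over the list alone. Ppara rose by 0.78 ± 0.16 and the thioesterase gene Acot4 by 1.33 ± 0.23, while Fgf21, a stress-induced hormone gene, fell by 2.44 ± 0.42. Lipid droplet genes differed by −0.08 (adjusted p = 0.249), with 2 of 21 higher and 4 lower, or 3 and 4 adjusted over the list alone. Lpl fell by 1.10 ± 0.18 and the fatty acid binding protein gene Fabp4 by 1.16 ± 0.23. Cholesterol synthesis genes differed by 0.30 (adjusted p = 0.464), with 2 of 25 higher and none lower over all genes and over the list alone, and by 0.047 to 0.37 when 1 library was left out.

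Of other lipid mediator enzymes, the list of other cytochrome P450 genes of arachidonic and linoleic acid fell by 0.52 (exact permutation adjusted p = 0.0265), with 3 of 16 higher and 4 lower over all genes and over the list alone. The other cytochrome P450 genes of arachidonic and linoleic acid list did not pass over the 11 libraries (−0.39, adjusted p = 0.106) or without KO 6 (adjusted p = 0.0501), and its adjusted p was 0.896 with an estimated correlation. Its median member differed by −0.02, and Cyp4a12a and Cyp4a12b were among the lower members while Cyp4f15 (0.57 ± 0.12) and Cyp2j11 (1.54 ± 0.27) rose. The list of epoxide hydrolases, lipoxygenases and prostanoid enzymes differed by −0.03 (adjusted p = 0.547), and by −0.059 to −0.0043 when 1 library was left out, with 3 of 24 higher and 3 lower over all genes and over the list alone. Hpgd, which inactivates prostaglandins, rose by 1.18 ± 0.19, and Alox5ap, needed for leukotriene synthesis, fell by 0.85 ± 0.14.

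Ribosomal, immediate early, unfolded protein and cell cycle lists were lower over 14 libraries. Cytosolic ribosomal protein genes fell by 0.37 (exact permutation adjusted p = 0.00418), with 35 of 43 lower and none higher, or 38 adjusted over the list alone, and every KO library below every WT library. Rpl28 fell by 0.64 ± 0.07 and Rpl37 by 0.50 ± 0.07, and the list fell by 0.31 over the 11 libraries, with 13 members lower. Immediate early genes, which respond within minutes to stimuli, fell by 0.49 (adjusted p = 0.00895), with 12 of 27 lower and none higher, or 14 adjusted over the list alone. Rhob fell by 0.59 ± 0.10, Egr2 by 1.10 ± 0.23 and Myc by 0.99 ± 0.22. The unfolded protein response list fell by 0.37 (adjusted p = 0.00557), with 6 of 30 lower and 1 higher, or 9 and 1 adjusted over the list alone. Its median member differed by −0.17, and over the 11 libraries 1 member was lower. Its lower members included Atf4, a transcription factor of amino acid stress (−0.51 ± 0.10), its target Asns (−3.22) and the glutathione-degrading enzyme gene Chac1 (−1.24 ± 0.31), of which Asns and Chac1 did not pass over the 11 libraries (adjusted p = 0.0854 and 0.0521). Cell cycle genes fell by 0.28 (adjusted p = 0.0490), with 7 of 37 lower and 1 higher, or 15 and 2 adjusted over the list alone; the mitotic activator gene Cdc20 fell by 0.85 ± 0.20 and the thymidine kinase gene Tk1 rose by 0.69 ± 0.17. The ribosomal, immediate early and unfolded protein lists passed over the 11 libraries (adjusted p = 0.0186 for each), the cell cycle list did not (adjusted p = 0.112), and with an estimated correlation the adjusted p was 0.324 for the first 2, 0.430 for the unfolded protein list and 0.560 for the cell cycle list. Of the 14 fits leaving out 1 library, the cell cycle and mitosis list passed in those without WT 3, KO 2 or KO 5, with adjusted p-values of 0.0522 to 0.0831 in the other 11.

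The remaining lists served mainly to follow other cell types. Markers of T and NK cells differed by −0.35 (exact permutation adjusted p = 0.214), of B and plasma cells by −0.64 (0.115), of dendritic cells and antigen presentation by −0.26 (0.129), of sinusoidal endothelium by −0.01 (0.926), of erythroid cells by −0.45 (0.121) and of mesothelium by 0.40 (0.405). When 1 library was left out, the B and plasma cell difference ran from −0.77 to −0.35 and passed without WT 1, and that of dendritic cells ran from −0.33 to −0.17 and passed without WT 2. The differences of T and NK cells ran from −0.44 to −0.20 and of mesothelium from 0.16 to 0.60. In the 10 libraries without WT 3 and Y-linked signal the differences were −0.13 for B and plasma cells, −0.099 for dendritic cells, −0.20 for T and NK cells and 0.28 for mesothelium. The list of pancreas, adipose, muscle and gallbladder epithelium markers, of which 3 were measured, fell by 1.42 (adjusted p = 0.0204), with 1 member lower over all genes and over the list alone. That member was the muscle troponin gene Tnnt3 (−3.57 ± 1.15), whose call held in 2 of the 14 fits that leave out 1 library, and the median member differed by −0.69. The list did not pass over the 11 libraries (−0.87, adjusted p = 0.106), and its adjusted p was 0.517 with an estimated correlation. In all, 23 of 43 lists differed between the groups over 14 libraries, 8 higher and 15 lower, and 19 over the 11 libraries, 7 higher and 12 lower. On the values as deposited 22 lists differed over 14 libraries, 5 higher and 17 lower.

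**Figure D4:**
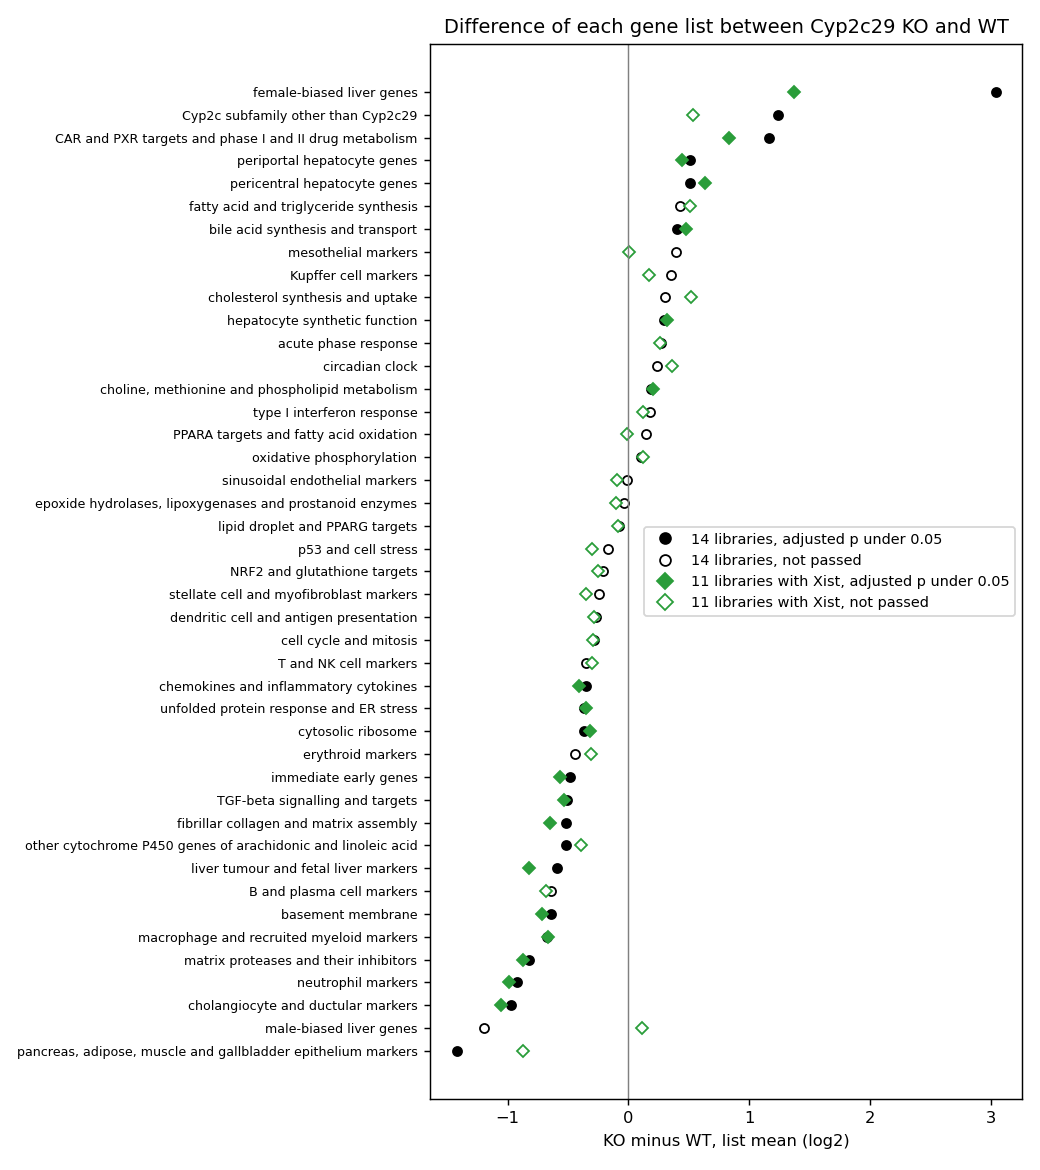
Difference in mean rescaled log2 expression between KO and WT for each of 43 gene lists, over 14 libraries (circles) and over the 11 libraries with Xist (diamonds). Filled symbols passed the exact permutation test at an adjusted p below 0.05, which 23 lists did over 14 libraries and 19 over the 11.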

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

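In 330 groups of 7 libraries, each a gene list or a named gene within WT or within KO, the gap of the highest or lowest library to the nearest other was set against Dixon's 95% limit, and 25 groups held a library beyond it. Chance alone does so in about 1 in 20 groups, and lists and genes of 1 library are not independent. KO 6 held 10 of the 25 and WT 3 held 6. All values in this part are rescaled log2 values, and no explanation was tested for them.

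KO 6 stood apart in 5 lists. Its value was 12.43 for the fatty acid and triglyceride synthesis list (other KO 11.30 to 11.70), 12.53 for the cholesterol synthesis and uptake list (11.28 to 11.78) and 12.28 for the choline, methionine and phospholipid metabolism list (12.03 to 12.13). It was 5.92 for the B and plasma cell markers list (6.67 to 7.18) and 5.95 for the list of pancreas, adipose, muscle and gallbladder epithelium markers (4.40 to 4.99). Among genes, KO 6 was highest of the KO libraries for Tafa2 (8.37, others up to 6.72), Cry1 (8.00, others up to 7.25), Arg1 (15.41, others up to 14.86), Acot4 (12.56, others up to 11.80) and Tnnt3 (7.27, others up to 2.47).

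WT 3 was lowest of the WT libraries for the pericentral hepatocyte genes list (10.95, others 11.92 to 12.25) and the cholesterol synthesis and uptake list (9.87, others 11.46 to 11.81), and highest for the NRF2 and glutathione targets list (12.00, others 11.51 to 11.69). It was also lowest for Cyp2c50 (10.77, others from 12.82), Cyp2c54 (5.67, others from 10.07) and the clock-controlled transcription factor gene Hlf (9.01, others from 9.63).

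WT 5 was lowest for the periportal hepatocyte genes list (13.21, others 13.76 to 14.13) and WT 4 for the unfolded protein response and ER stress list (11.34, others 11.56 to 11.63). KO 4 was lowest for the cytosolic ribosome list (12.24, others 12.43 to 12.53) and for its member Rpl28 (11.30, others from 11.55). KO 7 was lowest for Cyp3a41b (1.11, others from 7.76) and highest for Ccl21d (4.82, others up to 0.12). KO 2 was lowest for Cyp2c38 (11.35, others from 12.33), and KO 3 was lowest for Oat (14.34, others from 15.002) and highest for Cyp2j11 (7.15, others up to 6.29).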

How the results depend on the processing

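The settings as deposited, array quality weights, 11 libraries with Xist, the Y-linked term and 10 libraries without WT 3 were chosen after the data were seen. The fall of Cyp2c29 passed under every setting run. The number of changed genes was 3737, and 3699 to 3759 with median-ratio scaling, a stricter filter, other offsets or quality weights, and 2642 (without KO 6) to 4247 (without WT 1) when 1 library was left out. It was 2358 with no filter (1109 higher), where 43661 genes shared the adjustment, 2275 in the 11 libraries (1207 higher, 1068 lower), 2464 with the Y-linked term (1148 lower) and 964 in the 10 libraries (602 higher, 362 lower), the last 3 with fewer samples or residual degrees of freedom. As deposited, 1041 were higher and 3096 lower, with a median log2 difference of all genes of −0.157 against −0.0112 after rescaling.

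The fibrillar collagen and matrix assembly list kept its sign in every fit that gives a difference, at −0.59 to −0.44 when 1 library was left out, and was lost without KO 3 or KO 6. It missed the threshold at −0.51 with the replicate block (exact adjusted p = 0.0584), at −0.54 in the 10 libraries (0.0597), and with camera's estimated correlation (adjusted p = 0.402). The number of lists that differed was 23, and 17 to 25 when 1 library was left out. It was 0 in the 10 libraries, where the smallest exact p is 0.00833 and 18 lists had an unadjusted p below 0.05, and 0 with camera's estimated correlation, where 3 did. As a mean of z-scores 6 lists lost their call and 2 gained one. With fry 5 lost it and 2 gained one. The collagen list, left out of these counts, passed in both. The odds ratio for genes near Cyp2c29 was 1.23 with the stricter filter, 1.02 as deposited, 1.29 with the replicate block, 1.37 with the Y-linked term and 1.18 to 1.79 when 1 library was left out, and did not pass in the first 4; the cause was not tested. Of 12 relations between list means within the groups 4 passed, and 1 to 5 when 1 library was left out, 0 in the 11 and 0 in the 10 libraries, where WT has 4 and 3 animals, and 0 among KO animals alone; the last was chosen after the data were seen.

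No pairing of animals by replicate number was detected: deviations of equal numbers correlated at −0.04 to 0.08, and 1 of 7 numbers correlated best with its own. Deviations were taken from the mean of each group, with both WT classes together, so a weak pairing could be missed. With the replicate block 3303 genes and 20 lists passed, 9 higher and 11 lower. The circadian clock and erythroid lists gained a call there, while the collagen list and 4 others lost theirs.

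These lists did not pass over 14 libraries and changed sign or direction under a setting. The sinusoidal endothelial markers list was 0.076 as mean z, −0.049 to 0.028 when 1 library was left out, and had adjusted p = 0.799 and 0.896 with camera (preset and estimated correlation) and 0.859 with fry. The epoxide hydrolases, lipoxygenases and prostanoid enzymes list was 0.0539 with the stricter filter. The lipid droplet and PPARG targets list was 0.0497 as mean z, with adjusted p = 0.956 and 0.969 in camera. The PPARA targets and fatty acid oxidation list was −0.011 and −0.016 in the 11 and 10 libraries, the oxidative phosphorylation list −0.042 as deposited, and the male-biased liver genes list 0.11 in the 11 libraries. The mesothelial markers list was −0.15 with the stricter filter and −0.12 as mean z, with adjusted p = 0.799 and 0.896 in camera and 0.720 in fry. Cyp2c40 was −1.70 in the 11 libraries and with the Y-linked term and −2.22 in the 10, and passed as lower in the last 2 (limma adjusted p = 0.0443 and 0.0337). Cyp2c69 was −0.25, −0.25 and −1.003, and Cyp2c54 was −0.41 in the 10 libraries. When 1 library was left out, Cyp2c50 ran from −0.51 to 0.064 and Cyp2c54 from −0.15 to 0.84. The cause was not tested for these.

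Of 121 named genes, 97 kept their sign and their side of the threshold in the 11 libraries, 16 no longer passed, 6 passed there alone and 2 changed sign. A count-based fit, voom with sample weights and a length offset need counts or lengths and were not run. Depth per library is known from the protocol alone, so limits of detection are not given.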

Other observations

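Clock genes differed by 0.24 as a list over 14 libraries (exact permutation adjusted p = 0.115), with 5 of 19 members higher and none lower, or 8 and 1 adjusted over the list alone. The circadian clock list did pass with fry (adjusted p = 0.00174) and as a mean of z-scores (0.00964). It did not pass with camera's estimated correlation (adjusted p = 0.324). Cry2, a repressor of the clock, rose by 0.51 ± 0.08 and by 0.62 over the 11 libraries, and Hlf, an output transcription factor of the clock, rose by 1.12 ± 0.17. Cry1 fell by 2.33 over the 11 libraries but not over 14 (−1.18 ± 0.63, limma adjusted p = 0.199). Acute phase genes differed by 0.27 as a list (exact permutation adjusted p = 0.0641), with 6 of 28 higher and 1 lower, or 7 and 1 adjusted over the list alone. The list passed in 5 of the 14 fits that leave out 1 library (without WT 1, 2, 6 or 7 or KO 4). Hamp2, a hepcidin gene, rose by 2.79 ± 0.49 and the amyloid A gene Saa4 by 0.75 ± 0.16.

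Interferon response genes differed by 0.18 (exact permutation adjusted p = 0.249), and by 0.099 to 0.25 when 1 library was left out, with 5 of 29 higher and none lower, or 4 adjusted over the list alone, among them Ifit3b (0.85 ± 0.17). NRF2 and glutathione targets differed by −0.21 (adjusted p = 0.0665), with 5 of 28 lower and 1 higher, or 6 and 2 adjusted over the list alone, and it passed without KO 6 and on the values as deposited. G6pdx, the first enzyme gene of the pentose phosphate pathway, fell by 0.79 ± 0.12. The p53 list differed by −0.17 (adjusted p = 0.187), with 1 of 23 higher and none lower, or none adjusted over the list alone. Oxidative phosphorylation differed by 0.10 (adjusted p = 0.249), and by 0.057 to 0.14 when 1 library was left out, with 4 of 34 higher and none lower, or 3 adjusted over the list alone.

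The tests below on the sex of the groups, on the mix of cell types and on Cyp2c39 were chosen only after the results they bear on were seen. Over 14 libraries 3737 genes changed, and none of the other 99 splits drawn of the same libraries gave as many, with a highest of 2, so that 1 of 100 did, the real one. In the 11 libraries with Xist 2275 genes changed, and again 1 of 100 splits, the real one, gave as many. The highest other split gave 441, and it differs from the real one by exchanging WT 1 and KO 4. Neither count was reached by any other grouping of the libraries that was drawn.

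The matrix, ductular and myeloid lists were lower in KO, and unequal sex of the groups is a possible explanation, since 3 of the 7 WT libraries carry Y-linked signal. In the 11 libraries without them the differences were at least 0.986 times those over 14 and passed for all 3 lists. With WT 3 left out as well, the differences were at least 0.819 times those in the 11. The exact permutation p-values there were 0.0167, 0.0167 and 0.00833 before adjustment, and 0.00833 is the smallest possible. After adjustment no list passed without WT 3 (adjusted p = 0.0597 for the collagen list). The sizes of the differences argue against sex or that library as the whole cause. The adjusted test cannot settle this for WT 3, since it called no list there. A lower share of all cells other than hepatocytes would lower Kupffer and endothelial markers as much as ductular ones, but the difference in these lists exceeded that of the ductular list by 1.33 (exact permutation p = 0.00699) and 0.966 (p = 0.00117). The contrast was run against the ductular list alone, so a lower share of such cells was not tested for the matrix and myeloid lists. The Kupffer difference itself was 0.35 over 14 libraries and 0.016 in the 11 libraries less WT 3. Fewer ductular cells and fewer recruited myeloid cells, or lower expression per cell, stay open as explanations tied to the genotype, as do unrecorded differences between the groups such as litter or date.

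Female-biased genes were higher in KO, and the Y-linked signal in 3 WT libraries may account for part of this. The difference was 3.04 over 14 libraries and 1.37 over the 11 with Xist, where it still passed (exact permutation p = 0.00606), so the sex of those libraries does not account for the whole of it. Whether the remainder belongs to the genotype, to hormonal state or to strain background was not tested.

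Cyp2c39 was far higher in KO, and its reads could in part be those of Cyp2c29 types assigned to a paralog. Its value was 1.31% to 3.66% of the summed Cyp2c29 and Cyp2c29KO values in WT and 23.7% to 50.3% in KO, and in each KO library it was at least 6.48 times what the highest WT ratio would give, which argues against misassignment at the WT rate. A fixed share of the Cyp2c29KO transcript's reads going to Cyp2c39 cannot be told apart from real expression: over the 7 KO libraries r was 0.134 (exact permutation p = 0.774, 95% interval −0.689 to 0.806), rho was 0 (p = 1) and r without the 2 farthest libraries was −0.94, so that the interval still holds a strong relation. A regulatory or structural change at the locus in the knockout allele remains open and was not tested.

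Within each group of 7 animals the collagen and matrix list was set against 6 other lists, 12 relations adjusted together. The stellate list passed in both groups, with r = 0.969 in WT (exact permutation p = 0.000397, adjusted 0.00476) and 0.796 in KO (p = 0.00853, adjusted 0.0341), rho = 0.964 and 0.893 (adjusted 0.0111 and 0.0369), and r = 0.930 and 0.672 without the 2 libraries farthest from the median. The ductular list passed in WT at r = 0.898 (exact permutation p = 0.000794, adjusted 0.00476; rho = 0.964; 0.727 without 2), and in KO gave r = 0.804 (p = 0.0276, adjusted 0.0579; rho = 0.643; 0.841 without 2). The myeloid list passed in WT at r = 0.867 (exact permutation p = 0.0135, adjusted 0.0405), though rho = 0.857 did not (adjusted 0.0571), with 0.765 without 2, and in KO gave r = 0.260 (p = 0.586). The hepatocyte synthetic list gave r = −0.863 in WT (exact permutation p = 0.0290, adjusted 0.0579; rho = −0.964, adjusted 0.0111; −0.793 without 2) and −0.270 in KO (p = 0.499). The lipid droplet list gave r = −0.174 and −0.715 in WT and KO (exact permutation p = 0.659 and 0.0450, adjusted 0.791 and 0.0772; 0.0749 without 2 in KO), and the cell cycle list −0.0614 and −0.0579 (p = 0.877 and 0.915).

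WT holds 4 animals with Xist and 3 with Y-linked signal. With the means of these classes removed and 144 orders within them, a test chosen after the data were seen, the myeloid (r = 0.992), stellate (0.963) and hepatocyte synthetic (−0.907) lists passed in WT (exact permutation p = 0.00694 and adjusted 0.0256 for each), and the ductular list (0.913, p = 0.0208) did not after adjustment. The KO animals alone, adjusted over their own 6 relations, gave no relation that passed and 3 at an unadjusted exact permutation p below 0.05. Whether the relations differ between the groups was not tested.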
